A study of Homo sapiens with 12 samples.

How the data were processed

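The series measured RNA of IOSE80 cells, an immortalised line of normal human ovarian epithelial cells, after 28 days of exposure. Per the labels, the groups were 0.1% DMSO, bisphenol A (BPA) at 0.25 nM or at 2500 nM, and E2. BPA is a building block of plastics with weak oestrogenic activity, and E2 is the usual short name of estradiol. DMSO is taken here as the vehicle, though the treatment labels of the BPA and E2 groups name no solvent. The dose of E2 is not given in the sources used here. The labels list 12 samples. 11 libraries were analysed, 3 each for DMSO, BPA 0.25 nM and BPA 2500 nM and 2 for E2; E2 replicate 3 was not analysed here. Total RNA was taken up in Trizol and sequenced on an Illumina NovaSeq, per the labels' protocols. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

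The authors deposited 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per locus and library, with 2 decimals. HISAT, UMI-tools, StringTie and edgeR are listed in the submitters' processing notes, without versions, order or settings. Those notes name the build hg19. The coordinates in the files are nevertheless those of GRCh38: of 14123 Ensembl loci that are also in GENCODE 29, 74.8% have the same start and end, and positions are given on GRCh38 here. Each file lists 30574 loci, 14180 with an Ensembl identifier and 16394 with an identifier of a merged assembly (MSTRG). 1361 loci name several genes and 27 name none, and 415 are listed at 0 in every library. Whether the libraries kept the strand of the RNA is not given in the sources used here, so loci antisense to another gene are uncertain, as are loci that join several genes.

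Read depth is unknown, because the FPKM values show no steps of single reads. The FPKM totals lay between 206719 and 213663 per library, with 21223 to 23696 loci above 0, and these totals do not measure depth. Precision was therefore taken from the spread between libraries alone. The median standard error of a log2 fold change was 0.084 for BPA 2500 nM against DMSO and 0.094 for E2 against DMSO.

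Values were tested on the scale log2(FPKM + 1), on which the change of a low gene is understated. The 12182 loci with an FPKM of at least 1 in at least 2 libraries were tested; 9468 of them name exactly 1 protein-coding gene and 617 name several. A linear model with 1 mean per group was fitted to all 11 libraries with limma 3.58.1 in R 4.3.3, with moderated variances (trend and robust settings, statmod 1.5.0, 7 residual degrees of freedom, a median of 2.4 prior degrees of freedom). Tests were two-sided and adjusted by Benjamini-Hochberg within each of 6 comparisons, and a locus was called changed at an adjusted p under 0.05. A log2 change is given with its standard error (SE), and FPKM levels as mean ± standard deviation (SD). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

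39 gene lists were fixed (28 pathways, 3 of handling or RNA quality, 8 of cell types). Of their members, 828 matched a locus, 62 only a locus joined with another coding gene, and 62 no locus by that name. The 30 lists with at least 5 tested loci were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data and with fry. Camera compares a list with the other loci, while fry asks whether its own members move, on balance, in 1 direction. For each list the count of changed members is given over all loci and adjusted over the list alone.

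The genes, the lists, the tests and the first set of alternatives were chosen before the data were examined. For each comparison with DMSO the text names the 10 highest and 10 lowest called genes with no overlap between the libraries of both groups, or, where fewer than 5 passed in a direction, the 5 with the smallest p in that direction. It also takes its examples of each called list from the 4 members with the smallest p, not all of which are printed, and names the 5 most changed genes in each direction between treatments, and a panel of 20 genes of hormone response and cell state. The names skip clone and antisense symbols and loci with other than 1 coding gene, except among the list members. Genes named outside this rule are said to be so. A few genes that the rule takes are not reported here.

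Comparisons with the same DMSO libraries share their chance values. 100 sets of unchanged groups were therefore simulated with each locus's own residual spread, and the observed correlation, covariance and sign agreement of fold changes are given beside the simulated ones. The calling was tested on simulated data with 200 changed loci per comparison. For BPA 0.25 nM it recovered 32.8% of loci changed by 0.3 on the log2 scale, 74.6% of those changed by 0.6 and 95.5% of those changed by 1. The shares for BPA 2500 nM were 40.3%, 68.7% and 90.9%, and those for E2 17.9%, 68.7% and 86.4%. Of the unchanged loci, numbering 11783, 11758 and 11748, the calling picked 8, 11 and 8. In these simulated data loci varied independently of each other, and changes were put only into loci with a mean log2(FPKM + 1) above 1. Loci of real libraries may vary together, so recovery and false calls in these libraries may differ.

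The alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, libraries rescaled by the median of ratios, no trend or robust setting, only the groups compared in the fit, the replicate number as a block, a log2 fold change of at least 1 as a further condition, and leaving out each library in turn. Chosen after seeing the data were weights per library, the fit without both E2 libraries, list members by loci with a single name, each called list without its most changed member, and only loci naming 1 coding gene. Also chosen after seeing the data were camera and fry on the annotation terms that the series' own tables list per locus. The same holds for sets in which whole libraries' deviations from their group mean were dealt at random to the libraries. Such deviations cancel out within their own group, and those of both E2 libraries mirror each other. Dealt sets therefore hold correlations that separate libraries would not have, and their spread may be too wide. In both the simulated and the dealt sets as many top loci by p as were called were compared between comparisons, also after seeing the data. The removal of a smooth trend on GC content and transcript length from the fold changes was planned.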

Results

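RNA of IOSE80 cells, an immortalised line of normal human ovarian epithelial cells, was measured after 28 days with DMSO (n = 3), BPA 0.25 nM (n = 3), BPA 2500 nM (n = 3) or E2 (n = 2). The series title asks about injury by BPA at levels that people meet. The libraries were alike in total FPKM. Mitochondrial loci took 13.91 ± 0.36% of it in DMSO, 12.64 ± 0.02% with BPA 0.25 nM, 13.36 ± 0.37% with BPA 2500 nM and 13.13 ± 1.23% with E2 (mean ± SD). The DMSO libraries (13.63% to 14.31%) lay above all libraries of BPA 0.25 nM (12.62% to 12.66%) and just above those of BPA 2500 nM (12.94% to 13.62%). The median Pearson r of a library with the others, across loci on the log2 scale, lay between 0.979 and 0.983, except in E2 replicate 2, at 0.976. That library also had the lowest score on the first principal component (-18.4), which held 15.9% of the variance.

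The cells had almost no transcripts of the nuclear oestrogen receptors. ESR1 was listed at no more than 0.02 FPKM and ESR2 at no more than 0.04 FPKM in any library. GPER1, a membrane receptor that binds estradiol, stood at 2.19 ± 0.70 FPKM in DMSO (SD, n = 3). ESRRA, an orphan receptor related to the oestrogen receptors, stood at 14.9 ± 2.37 FPKM. The mesenchymal filament gene VIM was high at 718 ± 96.1 FPKM, while CDH1, the epithelial cadherin, did not exceed 0.02 FPKM. Of the ovarian surface list, ALDH1A1 (109 FPKM on average over the libraries), KRT18 (22.8), NR2F2 (3.19) and KRT8 (1.34) were present. Every other member with a matched locus, the larger part of the list, was too low to be tested. Among these, WT1, GATA4, MSLN, CALB2, UPK3B and BNC1 stood at 0.05 or less, KRT7 at 0.19 and KRT19 at 0.15. Of the fibroblast list, COL3A1 (28.7) and S100A4 (58.6) were present, with COL1A2 at 0.02 and DCN near 0. The leukocyte marker PTPRC and the endothelial marker CDH5 were near 0. FOXL2 of the granulosa list stood at 6.78 and EGFL7 of the endothelial list at 8.72. All 8 cell type lists had fewer than 5 tested loci and were not tested as lists, and neither were the metallothioneins.

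The first comparison asked what BPA 0.25 nM, the lower dose, changed against vehicle. Both genes that were called stood higher with BPA 0.25 nM. SZRD1 (MSTRG.240, chromosome 1, 16352575 to 16395406, plus strand), which encodes a small protein with a SUZ domain, went from 15.4 ± 2.96 to 31.5 ± 1.98 FPKM (SD, n = 3 each). Its log2 change was 1.0 ± 0.11 (SE; limma adjusted p = 0.0467). CCDC69 (MSTRG.15287, chromosome 5, 151181052 to 151224093, minus strand), which encodes a coiled-coil protein of the mitotic spindle midzone, went from 0.93 ± 0.12 to 2.24 ± 0.07 FPKM. Its log2 change was 0.75 ± 0.07 (adjusted p = 0.0103).

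The next genes by p did not pass with BPA 0.25 nM. The cell cycle kinase gene WEE1 stood at 4.24 ± 0.10 against 2.58 ± 0.18 FPKM in DMSO, PAK1IP1 at 24.9 ± 0.65 against 20.2 ± 0.95 and MRPL27 at 12.9 ± 0.14 against 10.5 ± 0.10 (adjusted p = 0.169 for each). On the lower side, also short of the threshold, were NUP43 (log2 change -0.52 ± 0.08), G3BP2 (-0.37 ± 0.06), TXNIP (-0.43 ± 0.07), GBP2 (-0.22 ± 0.04) and P4HA1 (-0.22 ± 0.04). Of 12182 loci, 2 were called by limma, and 1110 had an unadjusted p under 0.05, where 609 would by chance on average. That chance count varies more where loci vary together, so an excess over 609 is no test, here or in the comparisons below. Leaving out DMSO replicate 1, 2 or 3 gave 2, 4 and 9 calls. Without BPA 0.25 nM replicate 1, 2 or 3 the calls were 1, 0 and 2, without BPA 2500 nM replicate 1, 2 or 3 they were 4, 2 and 6, and without either E2 library 2. CCDC69 lost its call without BPA 0.25 nM replicate 1 or 2 (highest adjusted p 0.0894). SZRD1 lost it in 8 of the 11 fits, all but those without DMSO replicate 2 or 3 or BPA 2500 nM replicate 3 (highest adjusted p 0.161). Among other settings it also missed the threshold with only the groups compared in the fit (adjusted p 0.156), no filter on low values (0.0654), a mean FPKM of at least 5 (0.0511), rescaling (0.0593), no trend or robust setting (0.0644) and no E2 libraries (0.0826). With a pseudocount of 0.1 the log2 change of CCDC69 was 1.19.

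8 of the 30 lists moved with BPA 0.25 nM, and in none of them did a single member pass over all loci. The mitochondrial share of FPKM, 12.64% against 13.91% in DMSO, moved with this group as well. Ribosomal protein genes rose as a list (mean log2 change 0.12, 61 of 69 loci positive, camera adjusted p = 4.92e-13; adjusted p = 0.324 with an estimated correlation), with 1 member adjusted over the list alone. The mean was 0.075 without DMSO replicate 2. RPL5 stood at 141 ± 4.34 against 116 ± 9.67 FPKM, RPS19 at 136 ± 2.23 against 116 ± 8.38, RPL30 at 140 ± 4.90 against 122 ± 8.61 and RPL27 at 220 ± 16.1 against 188 ± 10.6. The list of oxidative phosphorylation rose (mean 0.10, 37 of 41 positive, adjusted p = 6.18e-07; adjusted p = 0.324 with an estimated correlation), with 0 members adjusted over the list alone. Its mean was 0.063 without DMSO replicate 2. UQCRH stood at 174 ± 7.05 against 140 ± 20.4 FPKM, UQCRC1 at 69.5 ± 2.20 against 62.4 ± 1.79, NDUFS8 at 10.8 ± 0.55 against 8.64 ± 0.97 and ATP5MC3 at 52.0 ± 2.58 against 46.1 ± 3.01. DNA replication genes rose (mean 0.11, 24 of 27 positive, adjusted p = 1.54e-05; adjusted p = 0.324 with an estimated correlation), with 1 member adjusted over the list alone. Among them MCM7 stood at 64.7 ± 0.60 against 56.3 ± 1.56 FPKM, CDC45 at 14.4 ± 0.79 against 12.3 ± 0.82, MCM4 at 27.8 ± 3.16 against 23.2 ± 1.20 and MCM3 at 60.9 ± 7.30 against 51.5 ± 3.55. Heat shock genes rose (mean 0.13, 12 of 12 positive, adjusted p = 0.00189; adjusted p = 0.324 with an estimated correlation), with 0 members adjusted over the list alone. HSPA8 stood at 377 ± 53.2 against 310 ± 3.09 FPKM and HSP90AA1 at 266 ± 12.8 against 230 ± 19.9.

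4 further lists moved with BPA 0.25 nM, along with the lower mitochondrial share. Genes of the NRF2 response to oxidative stress rose (mean 0.07, 14 of 18 positive, adjusted p = 0.0182; adjusted p = 0.324 with an estimated correlation), with 0 members adjusted over the list alone. SRXN1 stood at 20.8 ± 0.33 against 18.4 ± 0.76 FPKM and TXN at 183 ± 2.58 against 168 ± 6.75. The NRF2 call was lost without DMSO replicate 2 or BPA 0.25 nM replicate 2 or 3 (highest adjusted p 0.143). Antioxidant enzymes rose (mean 0.05, 14 of 16 positive, adjusted p = 0.0212; adjusted p = 0.524 with an estimated correlation), with 0 members adjusted over the list alone. GSS stood at 11.9 ± 1.22 against 10.4 ± 0.39 FPKM and PRDX6 at 208 ± 6.32 against 195 ± 8.30. This call was lost without DMSO replicate 1 or 2 or BPA 0.25 nM replicate 2 or 3 (highest adjusted p 0.286), and with a mean FPKM of at least 5 (adjusted p 0.112). The mean was 0.018 without DMSO replicate 2, 0.085 without DMSO replicate 3, 0.084 and 0.019 without BPA 0.25 nM replicate 1 and 2, and 0.08 without its most changed member, GPX8. Genes of glycolysis and hypoxia fell (mean -0.10, 14 of 22 negative, adjusted p = 0.0102; adjusted p = 0.324 with an estimated correlation), 3 of them adjusted over the list alone. P4HA1 stood at 20.9 ± 0.63 against 24.4 ± 0.40 FPKM, BNIP3 at 27.5 ± 0.23 against 32.5 ± 1.80 and the glucose transporter gene SLC2A3 at 4.88 ± 0.46 against 6.11 ± 0.21. The list call was lost without DMSO replicate 3 (adjusted p 0.124), and with a mean FPKM of at least 5 the mean was -0.038 (adjusted p 0.176). Mitochondrially encoded mRNAs fell (mean -0.17, 5 of 5 negative, adjusted p = 0.0102; adjusted p = 0.324 with an estimated correlation), 2 of them adjusted over the list alone. MT-ND3 stood at 1959 ± 46.9 against 2222 ± 160 FPKM. The largest change was at MSTRG.18624 (-0.45 ± 0.14), a minus-strand locus that joins MT-ND4, MT-ND5, MT-ND6, MT-CO3 and a tRNA gene and is uncertain for that reason, and 2 of the other 4 loci join several genes too. Without it, a test chosen after seeing the data, the mean was -0.104 and the call was lost (adjusted p 0.0677). With no filter on low values it was lost as well (adjusted p 0.244). The list of mitochondrial mRNAs was set up for handling or RNA quality, and the lower mitochondrial share comes in part from the same loci. Whether handling or RNA quality differed between the groups was not tested.

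The second comparison asked what BPA 2500 nM, the higher dose, changed against vehicle. In that comparison 158 loci were called, 49 higher and 109 lower with BPA 2500 nM. Most differed by a modest amount (median size 0.36 on the log2 scale). DMSO is the only vehicle group, so a difference from it may lie with the DMSO cultures. SZRD1 and CCDC69 were again higher, at 31.9 ± 1.57 and 2.09 ± 0.17 FPKM (log2 changes 1.02 ± 0.11 and 0.68 ± 0.07). AMOTL2 (MSTRG.13491, chromosome 3, 134351852 to 134374560, minus strand, a locus that also names the pseudogene RPL39P5) encodes an adaptor of Hippo signalling. It rose from 4.50 ± 0.14 to 8.37 ± 0.26 FPKM (log2 change 0.77 ± 0.08, adjusted p = 0.00281). ODC1 (MSTRG.10380, chromosome 2, 10439968 to 10448327, minus strand), the rate-limiting enzyme of polyamine synthesis, rose from 73.8 ± 1.70 to 97.8 ± 1.72 FPKM (0.40 ± 0.03, adjusted p = 0.00217). KCTD10 (MSTRG.4646, chromosome 12, 109448655 to 109477305, minus strand), a substrate adaptor of cullin ubiquitin ligases, fell from 7.17 ± 0.11 to 3.59 ± 0.30 FPKM (-0.83 ± 0.06, adjusted p = 0.000743).

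NOP16 (log2 change 0.45 ± 0.06), RRP9 (0.43 ± 0.06), NOL6 (0.42 ± 0.06) and NOP56 (0.42 ± 0.05), which encode nucleolar proteins, were among the 10 highest genes with BPA 2500 nM. So were the phosphatase gene DUSP2 (0.45 ± 0.08) and a locus named TNN (MSTRG.1579, 0.50 ± 0.07) that lies on the strand opposite to its annotated gene. TXNIP (MSTRG.1171, chromosome 1, 145992435 to 145996600, minus strand), a thioredoxin-binding protein that responds to glucose, fell from 9.45 ± 0.59 to 5.08 ± 0.35 FPKM (-0.78 ± 0.07, adjusted p = 0.00281). The glutathione transferase gene GSTA4 fell from 16.0 ± 1.04 to 8.98 ± 1.81 FPKM (-0.78 ± 0.11, adjusted p = 0.0154). The cyclin gene CCNG2 fell from 3.84 ± 0.25 to 2.02 ± 0.22 FPKM and the methionine synthase gene MTR from 7.05 ± 0.62 to 4.22 ± 0.21. CAMK2N1, an inhibitor of calmodulin-dependent kinase, fell from 5.82 ± 0.45 to 3.61 ± 0.06 FPKM. The retinoic acid-binding protein gene CRABP2 fell from 6.39 ± 0.56 to 4.09 ± 0.20 and TUBB4A from 4.08 ± 0.12 to 2.53 ± 0.32. ZNF324B (-0.58 ± 0.11) and IGIP (-0.53 ± 0.09) also fell. With a pseudocount of 0.1 these were -1.11 (adjusted p 0.053) and -0.99, and CCDC69 was at 1.09. At the planned pseudocount adjusted p was 0.0438 for ZNF324B, 0.0336 for IGIP, 0.0353 for TUBB4A and 0.0423 for DUSP2.

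By limma 2098 of the 12182 loci had an unadjusted p under 0.05 for BPA 2500 nM, where 609 would by chance on average. Of the 158 calls, 3 changed by at least 1 on the log2 scale. After rescaling the libraries by the median of ratios, 150 loci were called, 72 up and 78 down, so the excess of lower genes depended on the scaling. Leaving out DMSO replicate 1, 2 or 3 gave 38, 53 and 83 calls and kept 14, 15 and 19 of the 24 calls named for this comparison. The counts were 68, 75 and 73 (19, 21 and 19 kept) without BPA 0.25 nM replicate 1, 2 and 3. They were 32, 32 and 43 (12, 11 and 16 kept) without BPA 2500 nM replicate 1, 2 and 3, and 249 and 251 (24 and 24 kept) without E2 replicate 1 and 2. AMOTL2, CAMK2N1, CCDC69, CCNG2, ID2, KCTD10, NOP16, ODC1, SZRD1 and TXNIP kept their calls in each of these 11 fits. DUSP2 and IGIP lost theirs in 9, P4HA1, TUBB4A and ZNF324B in 8, MTR and RRP9 in 5, CRABP2, GSTA4, NOL6 and the TNN locus in 3, and IFIT1, NOP56 and SLC2A3 in 2. Of the 24, 11 lost theirs with no filter on low values and 20 with only the groups compared in the fit, among them CAMK2N1 and CCNG2 (adjusted p 0.0529 each), ID2 (0.0588) and CCDC69, NOP16 and SZRD1 (0.0594 each).

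**Figure D1:**
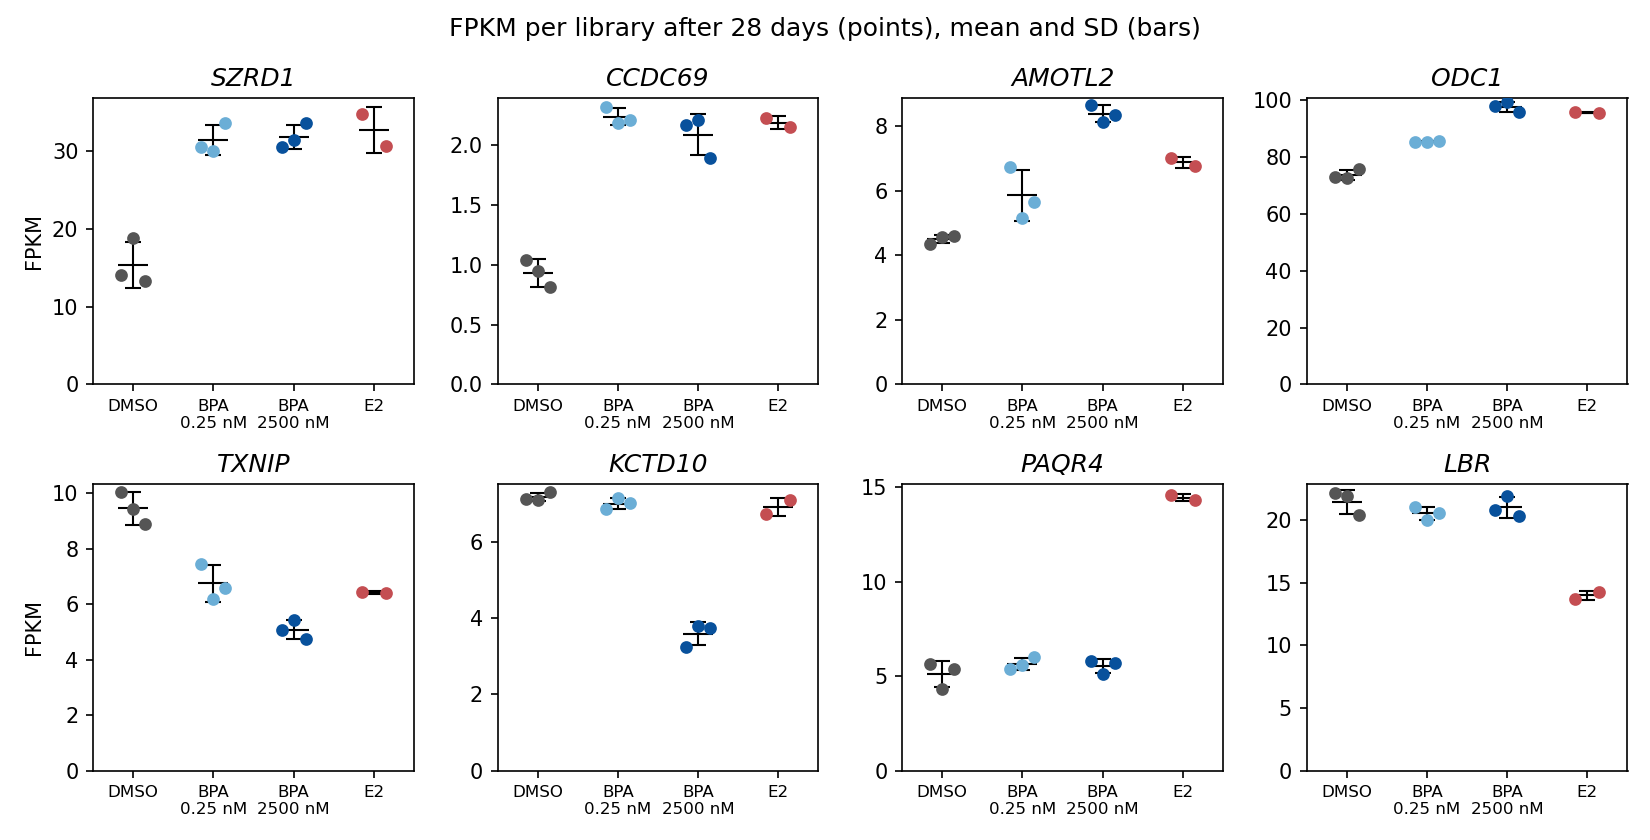
FPKM of 8 genes per library (points) with group mean and SD (bars), by group on the horizontal axis and FPKM from 0 on the vertical axis. SZRD1 and CCDC69 stand apart in DMSO, KCTD10 is low with BPA 2500 nM (3.59 ± 0.30 FPKM), and with E2 PAQR4 is high (14.4 ± 0.20 FPKM) and LBR low (13.98 ± 0.38 FPKM).

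10 of the 30 lists moved with BPA 2500 nM, where the mitochondrial share of FPKM was 13.36% against 13.91% in DMSO. Heat shock genes rose (mean log2 change 0.16, 12 of 12 positive, camera adjusted p = 3.24e-05; adjusted p = 0.213 with an estimated correlation), with 0 members over all loci and 4 adjusted over the list alone. The chaperone gene HSP90AB1 stood at 1092 ± 29.5 against 1004 ± 23.1 FPKM, HSPD1 at 316 ± 13.0 against 276 ± 15.2 and DNAJB1 at 42.9 ± 1.66 against 34.5 ± 2.64. Interferon response genes fell (mean -0.14, 20 of 22 negative, adjusted p = 0.000316; adjusted p = 0.213 with an estimated correlation). Over all loci 1 fell, IFIT1 (from 15.3 ± 0.23 to 12.2 ± 0.16 FPKM), and 5 fell adjusted over the list alone. IFIT1 lost its call without BPA 2500 nM replicate 1 or 2 (highest adjusted p 0.058) and with only the groups compared (0.0594). IFIT2 stood at 10 ± 0.56 against 12.9 ± 1.15 FPKM and IFIT3 at 6.35 ± 0.38 against 7.61 ± 0.16. Genes of glycolysis and hypoxia fell (mean -0.16, 18 of 22 negative, adjusted p = 0.0161; adjusted p = 0.221 with an estimated correlation). Over all loci 2 fell, SLC2A3 (from 6.11 ± 0.21 to 4.13 ± 0.16 FPKM) and P4HA1 (from 24.4 ± 0.40 to 20.5 ± 0.35), and 6 adjusted over the list alone. P4HA1 (adjusted p = 0.0331) lost its call in 8 of 11 fits without 1 library, with no filter on low values (0.0806) and with only the groups compared (0.0798). SLC2A3 lost it without BPA 2500 nM replicate 1 or 2 (highest adjusted p 0.0626) and with only the groups compared (0.0529). That list lost its call without DMSO replicate 3 or BPA 2500 nM replicate 2 (highest adjusted p 0.0889), and with a mean FPKM of at least 5 its mean was -0.088 (adjusted p 0.135). Targets of TGF-beta rose (mean 0.09, 9 of 14 positive, adjusted p = 0.0106; adjusted p = 0.382 with an estimated correlation). Over all loci 1 rose, ID2 (from 36.5 ± 0.91 to 47.7 ± 1.56 FPKM), and adjusted over the list alone 5 rose and 1 fell. CCN2 stood at 14.9 ± 0.32 against 11.8 ± 0.92 FPKM and SMAD6 at 4.35 ± 0.09 against 3.52 ± 0.20. The call was lost without BPA 2500 nM replicate 3 (adjusted p 0.0622) and with a mean FPKM of at least 5 (adjusted p 0.152), and the mean was 0.06 with no filter on low values.

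Genes of epithelial junctions and keratins fell with BPA 2500 nM (mean -0.15, 8 of 9 negative, adjusted p = 0.0291; adjusted p = 0.221 with an estimated correlation), with 0 members over all loci and 1 adjusted over the list alone. Of the 27 genes listed only 9 loci were tested, and CDH1, KRT7 and KRT19 were among those too low. The desmosome genes DSG2 and DSP stood at 7.39 ± 0.47 against 9.63 ± 0.67 and 1.5 ± 0.15 against 1.88 ± 0.08 FPKM. The call was lost without DMSO replicate 3 or BPA 2500 nM replicate 2 (highest adjusted p 0.187) and with a mean FPKM of at least 5 (adjusted p 0.0707), and with no filter on low values the mean was -0.065 (adjusted p 0.289). Without DSG2, the most changed member, adjusted p was 0.0938. Matrix proteases and their inhibitors fell (mean -0.12, 12 of 15 negative, adjusted p = 0.0291; adjusted p = 0.289 with an estimated correlation), with 0 members over all loci and 4 adjusted over the list alone. PLAUR stood at 3.17 ± 0.32 against 4.35 ± 0.49 FPKM and MMP10 at 253 ± 5.91 against 278 ± 8.32. This call was lost without DMSO replicate 3 (adjusted p 0.0704), after rescaling (adjusted p 0.0557) and with a mean FPKM of at least 5 (adjusted p 0.062). With no filter on low values the mean was -0.081 (adjusted p 0.289), and without PLAUR, the most changed member, adjusted p was 0.0774.

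The remaining 4 lists rose with BPA 2500 nM, with 0 members over all loci in each. Ribosomal proteins had a mean of 0.05 (55 of 69 positive, adjusted p = 9.45e-05; adjusted p = 0.648 with an estimated correlation), and the call was lost without DMSO replicate 2, where the mean was 0.009 (adjusted p 0.0702). The mean was 0.087 without DMSO replicate 3 and 0.084 after rescaling. DNA replication had a mean of 0.07 (21 of 27 positive, adjusted p = 0.00111; adjusted p = 0.382 with an estimated correlation), and 0.036 without BPA 2500 nM replicate 2. Oxidative phosphorylation had a mean of 0.03 (28 of 41 positive, adjusted p = 0.0185; adjusted p = 0.648 with an estimated correlation). It was lost without DMSO replicate 2 or BPA 2500 nM replicate 2 (highest adjusted p 0.326), and with a mean FPKM of at least 5 (adjusted p 0.14). Its mean was -0.013 without DMSO replicate 2, 0.014 without BPA 2500 nM replicate 2, 0.054 without DMSO replicate 1, 0.056 after rescaling and 0.014 with array weights. The NRF2 list had a mean of 0.05 (13 of 18 positive, adjusted p = 0.045; adjusted p = 0.382 with an estimated correlation). It was lost without DMSO replicate 2 or 3, BPA 0.25 nM replicate 2 or BPA 2500 nM replicate 1 or 3 (highest adjusted p 0.202). The mean was 0.092 with a mean FPKM of at least 5 and 0.082 after rescaling. Adjusted over the list alone 0, 1 and 0 rose in the first 3, and in the NRF2 list 1 rose and 2 fell. RPL5 stood at 136 ± 1.43 against 116 ± 9.67 FPKM, MCM7 at 64.8 ± 1.60 against 56.3 ± 1.56, TYMS at 116 ± 1.43 against 96.9 ± 9.34, ATP5MC1 at 27.4 ± 0.99 against 23.7 ± 2.06 and UQCRC1 at 67.6 ± 1.78 against 62.4 ± 1.79. On the lower side, SDHC of oxidative phosphorylation stood at 10.1 ± 1.29 against 11.7 ± 0.77 FPKM and ME1 of the NRF2 list at 19.5 ± 0.24 against 22.2 ± 0.99. Also of that list, SRXN1 stood at 21.3 ± 0.34 against 18.4 ± 0.76 FPKM and the cystine transporter gene SLC7A11 at 2.08 ± 0.10 against 3.05 ± 0.51.

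The third comparison set E2 against vehicle, with 2 E2 libraries. Between these groups 51 loci were called, 20 higher and 31 lower with E2. PAQR4 (MSTRG.6823, chromosome 16, 2969245 to 2973489, plus strand), a member of the progestin and adipoQ receptor family, rose from 5.11 ± 0.68 (SD, n = 3) to 14.4 ± 0.20 FPKM (n = 2). Its log2 change was 1.34 ± 0.09 (SE; limma adjusted p = 0.00107). LBR (MSTRG.1860, chromosome 1, 225401502 to 225428855, minus strand), the lamin B receptor of the inner nuclear membrane, fell from 21.5 ± 0.95 to 13.98 ± 0.38 FPKM (-0.58 ± 0.05, adjusted p = 0.00404). SZRD1 and CCDC69 were higher here too, at 32.8 ± 2.95 and 2.19 ± 0.06 FPKM (log2 changes 1.05 ± 0.13 and 0.72 ± 0.07). So were AMOTL2 (0.52 ± 0.09), NOP16 (0.42 ± 0.06), ID2 (0.38 ± 0.05) and ODC1 (0.37 ± 0.04). A locus of 262 bases named YWHAE (MSTRG.7706, chromosome 17, 1344629 to 1344890, plus strand) lies on the strand opposite to the annotated gene. It was listed at 7.41 and 19.8 FPKM in the E2 libraries and at 0 in the other 9 (limma adjusted p = 0.00107). The libraries at 0 show no spread, so the pooled spread behind this p-value understates that of the E2 libraries.

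WDR3 (log2 change 0.39 ± 0.07) and DDX21 (0.37 ± 0.05), which encode nucleolar proteins, completed the 10 highest genes with E2. Among the lowest, NKRF, which encodes a repressor of NF-kB targets, fell from 5.16 ± 0.34 to 2.42 ± 0.87 FPKM (-0.87 ± 0.13, adjusted p = 0.0309). PHLDA3, a p53 target at a locus that also names AC096677, fell from 10.6 ± 0.58 to 5.78 ± 1.63 FPKM (-0.80 ± 0.12, adjusted p = 0.0351). The phosphatase gene CTDSP1 fell from 11.3 ± 0.70 to 7.60 ± 0.72 FPKM, the chemokine receptor gene CCR10 from 8.01 ± 0.29 to 5.28 ± 0.11 and PBXIP1 from 7.92 ± 0.58 to 5.28 ± 0.62. TSPYL2 fell from 8.70 ± 1.12 to 5.72 ± 0.29 FPKM, the small GTPase gene RRAS from 35.2 ± 2.17 to 24.3 ± 2.97, the nucleoporin gene NUP43 from 14.6 ± 1.62 to 9.92 ± 0.03 and TCTE3 from 1.29 ± 0.06 to 0.47 ± 0.13. These 7 passed with adjusted p = 0.0242, 0.0438, 0.0374, 0.0471, 0.0351, 0.0451 and 0.0316, in the order given. With a pseudocount of 0.1 the log2 change was -1.31 for TCTE3 (-0.64 with 1), 1.15 for CCDC69 and 6.93 for the YWHAE locus (3.73 with 1).

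For E2 limma found 1878 of 12182 loci with an unadjusted p under 0.05, where 609 would by chance on average. Of the 51 calls, 4 changed by at least 1 on the log2 scale. After rescaling by the median of ratios 50 were called, 25 up and 25 down. Without DMSO replicate 1, 2 or 3 the count was 9, 16 and 13 (5, 6 and 8 of the 20 calls named for E2 kept). Without BPA 0.25 nM replicate 1, 2 or 3 it was 19, 12 and 35 (9, 7 and 13 kept), and without BPA 2500 nM replicate 1, 2 or 3 it was 25, 7 and 21 (8, 5 and 8 kept). It was 190 and 34 (14 and 10 kept) without E2 replicate 1 and 2, where the lone E2 library was assumed to vary like the other groups. CCDC69, LBR, ODC1, PAQR4 and the YWHAE locus kept their calls in each of these fits. For the YWHAE locus that is no check, since its only spread lies between the E2 libraries. Without either of them no spread is left, and every other library was listed at 0. TSPYL2 lost its call in all 11, AMOTL2, CCR10, NUP43, PBXIP1, RRAS, TCTE3 and WDR3 in 10, DDX21, NOP16 and PHLDA3 in 9, NKRF in 8, CTDSP1 in 5, ID2 in 4 and SZRD1 in 2. All 20 lost their calls with only the groups compared in the fit, these 5 with adjusted p 0.18, 0.166, 0.248, 0.0766 and 0.163. Of the 20, 11 lost theirs with no filter on low values and 16 with array weights.

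7 of the 30 lists moved with E2. DNA replication genes rose (mean log2 change 0.11, 21 of 27 positive, camera adjusted p = 8.52e-05; adjusted p = 0.258 with an estimated correlation), with 0 members over all loci and 0 adjusted over the list alone. CDC45 stood at 14.5 ± 0.02 against 12.3 ± 0.82 FPKM and MCM10 at 13.0 ± 0.30 against 11.3 ± 0.16. Mitosis genes rose (mean 0.11, 24 of 26 positive, adjusted p = 0.000319; adjusted p = 0.326 with an estimated correlation), with 0 members over all loci and 0 adjusted over the list alone. CCNA2 stood at 83.8 ± 8.66 against 70.8 ± 2.91 FPKM and KIF20A at 24.9 ± 0.66 against 22.2 ± 1.0. The mitosis call was lost without E2 replicate 2, where the mean was 0.051 (adjusted p 0.145), and without E2 replicate 1 the mean was 0.17. Heat shock genes rose (mean 0.14, 9 of 12 positive, adjusted p = 0.000274; adjusted p = 0.258 with an estimated correlation), with 0 members over all loci and 6 adjusted over the list alone. HSP90AA1 stood at 299 ± 5.34 against 230 ± 19.9 FPKM and DNAJA1 at 186 ± 12.3 against 162 ± 7.21. DNA damage repair genes rose (mean 0.06, 19 of 27 positive, adjusted p = 0.0414; adjusted p = 0.559 with an estimated correlation), with 0 members over all loci and 0 adjusted over the list alone. FANCD2 stood at 9.45 ± 0.27 against 8.24 ± 0.35 FPKM. The repair call was lost without DMSO replicate 1, BPA 0.25 nM replicate 3 or E2 replicate 2 (highest adjusted p 0.863), with a mean FPKM of at least 5 (0.197) with only the groups compared (0.0619) and without XRCC5, the most changed member (0.0659). Its mean was -0.006 without E2 replicate 2 and 0.118 without E2 replicate 1.

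Genes of glycolysis and hypoxia fell with E2 (mean -0.21, 19 of 22 negative, adjusted p = 0.000131; adjusted p = 0.135 with an estimated correlation), with 0 members over all loci and 7 adjusted over the list alone. The mitophagy gene BNIP3L stood at 11.3 ± 4.72 against 22.8 ± 1.45 FPKM, BNIP3 at 25.8 ± 0.13 against 32.5 ± 1.80 and ALDOC at 18.7 ± 2.94 against 27.7 ± 1.61. Matrix proteases and their inhibitors fell (mean -0.15, 13 of 15 negative, adjusted p = 0.0036; adjusted p = 0.249 with an estimated correlation), with 0 members over all loci and 3 adjusted over the list alone. PLAT stood at 4.18 ± 0.02 against 5.05 ± 0.15 FPKM and MMP10 at 249 ± 5.93 against 278 ± 8.32. With a mean FPKM of at least 5 the mean of this list was -0.088 (adjusted p 0.0873). Interferon response genes fell (mean -0.10, 16 of 22 negative, adjusted p = 0.0206; adjusted p = 0.258 with an estimated correlation), with 0 members over all loci and 4 adjusted over the list alone. ISG20 stood at 0.62 ± 0.11 against 1.12 ± 0.15 FPKM and IFI6 at 9.71 ± 0.82 against 12.8 ± 1.55. This call was lost without DMSO replicate 1 or E2 replicate 2 (highest adjusted p 0.169) and with single-name list members, an alternative chosen after seeing the data (adjusted p 0.0598), or without ISG20, the most changed member (adjusted p 0.0543). Over the 3 comparisons with DMSO, camera called 8, 10 and 7 lists, 0 of them with an estimated correlation.

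Fry, which asks only whether a list's own members move on balance in 1 direction, called 0, 6 and 7 lists, and these were in part others. It does not set a list against the other loci, so a shift of all loci bears on it. The median log2 change of all loci was -0.027 with BPA 2500 nM and -0.007 with E2, and fry was not rerun after rescaling. With BPA 2500 nM it called heat shock, interferon response, glycolysis and hypoxia, epithelial junctions and matrix proteases. It did not call ribosomal proteins (fry adjusted p = 0.352), DNA replication (0.119), oxidative phosphorylation (0.508), NRF2 (0.128) or TGF-beta targets (0.0887). It also called inflammatory cytokines of the NF-kB list, which camera did not (mean -0.08, 5 of 8 negative, fry adjusted p = 0.0244, camera adjusted p = 0.302). With E2 it called DNA replication, heat shock, glycolysis and hypoxia, matrix proteases and interferon response, but not mitosis (fry adjusted p = 0.107) or DNA damage repair (0.34). Cholesterol synthesis (mean -0.07, 15 of 21 negative, fry adjusted p = 0.0136, camera adjusted p = 0.213) and fatty acid metabolism (mean -0.06, 16 of 21 negative, fry adjusted p = 0.024, camera adjusted p = 0.196) were called with E2 by fry alone.

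**Figure D2:**
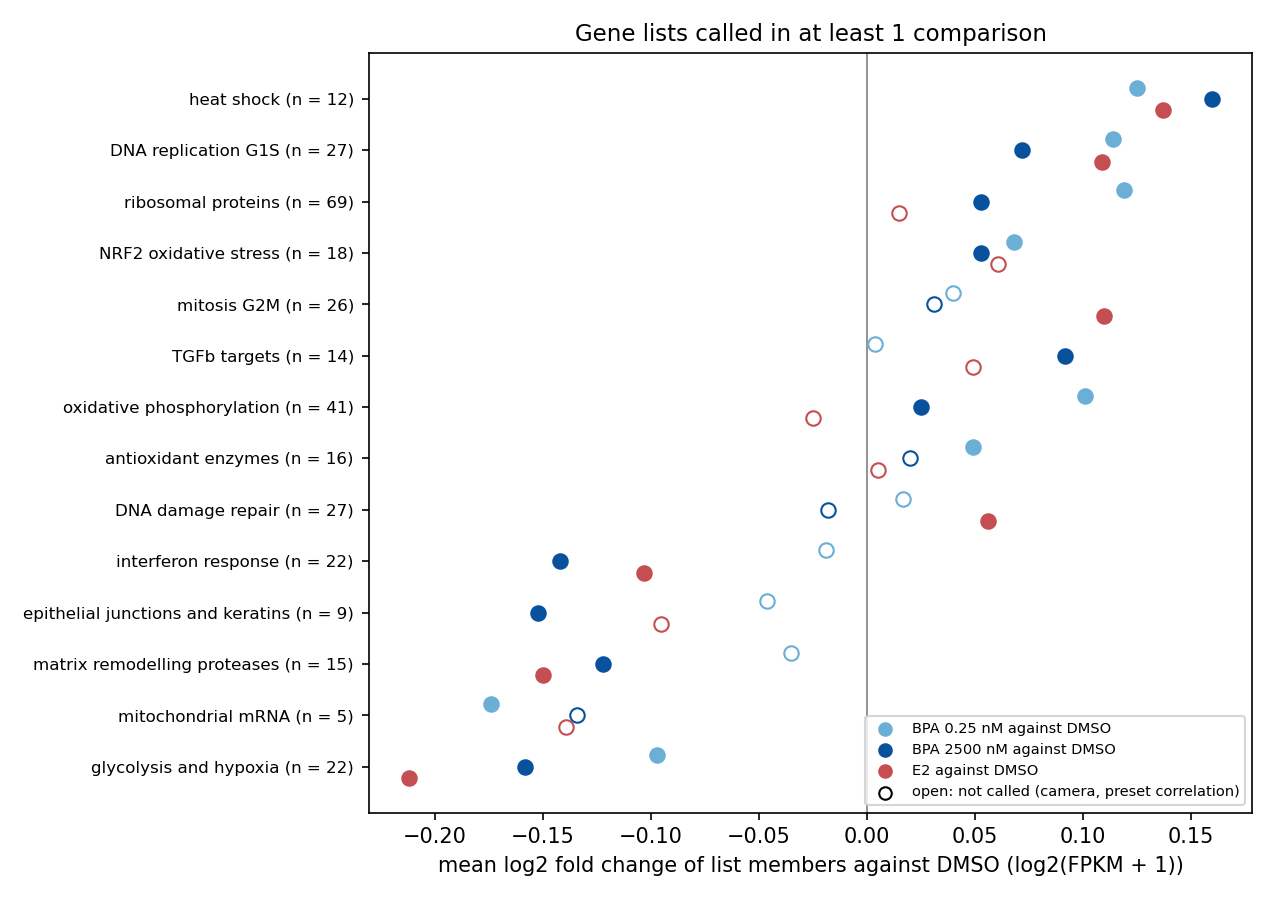
Mean log2 fold change against DMSO (horizontal axis) of the members of each list called in at least 1 comparison (vertical axis, n loci), for BPA 0.25 nM, BPA 2500 nM and E2; filled points were called by camera with the preset correlation, open points were not. Glycolysis and hypoxia genes lie at -0.10, -0.16 and -0.21 in the 3 comparisons and heat shock genes at 0.13, 0.16 and 0.14.

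The oestrogen response list was not called in any comparison (20 loci, camera adjusted p = 0.974 for BPA 0.25 nM, 0.611 for BPA 2500 nM and 0.995 for E2). Its mean log2 changes were -0.004, 0.025 and 0.001 (medians -0.002, -0.006 and 0.011), with 9, 9 and 12 members positive and 11, 11 and 8 negative. Over all loci 0 members passed. Adjusted over the list alone 0, 1 and 2 fell: STC2 with BPA 2500 nM (log2 change -0.44 ± 0.09), and STC2 (-0.42 ± 0.10) and ADCY9 (-0.28 ± 0.06) with E2, both named after seeing the data. The mixed test of fry, which asks whether members move in either direction, gave unadjusted p of 0.522, 5.43e-05 and 0.00096. For BPA 2500 nM and E2 that test gave smaller unadjusted p in other lists that camera did not call. Mesenchymal genes had 3.57e-08 and 2.24e-06, and targets of YAP and TEAD 8.16e-09 and 4.93e-08. The mixed test therefore does not set the oestrogen response list apart. None of the tested panel genes passed. ESRRA stood at 19.3 ± 1.72, 19.7 ± 1.17 and 19.5 ± 1.82 FPKM in the treated groups against 14.9 ± 2.37 in DMSO (limma adjusted p = 0.441, 0.123 and 0.192). Its log2 changes were 0.37 ± 0.11, 0.39 ± 0.11 and 0.38 ± 0.12. The 95% interval of the log2 change with E2 was -0.54 to 0.51 for GPER1, -0.47 to -0.05 for CYP1A1 and -0.34 to 0.07 for CYP1B1 (adjusted p = 0.991, 0.222 and 0.541). It was -0.21 to 0.15 for HMOX1, -0.28 to 0.28 for the proliferation marker MKI67 and -0.37 to 0.26 for VIM (adjusted p = 0.901, 0.995 and 0.897). The panel genes AHR, GREB1 and CDKN1A were too low to be tested, at 0.03, 0.08 and 0.67 FPKM in DMSO, and ESRRG, PGR, NR1I2, TFF1 and IL6 were not analysed here.

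The treatments were also set against each other. BPA 2500 nM differed from BPA 0.25 nM in 8 loci, 2 higher and 6 lower (3 and 3 after rescaling). KCTD10 was lower at the higher dose by -0.80 ± 0.06 on the log2 scale (adjusted p = 0.00105). So were CAMK2N1 (-0.45 ± 0.06), PDLIM3 (-0.45 ± 0.06), COL3A1 (-0.43 ± 0.05), a fibrillar collagen gene and fibroblast marker, and the receptor gene CALCRL (-0.38 ± 0.05). CCN1, a secreted matrix protein, was higher (0.36 ± 0.05, adjusted p = 0.0413). E2 stood apart from both BPA doses in PAQR4, which was lower with BPA by -1.22 ± 0.09 at 0.25 nM and -1.24 ± 0.09 at 2500 nM. LBR was higher with BPA by 0.52 ± 0.05 and 0.56 ± 0.05, and CTDSP1 by 0.58 ± 0.07 and 0.68 ± 0.07. The YWHAE locus was called in both as well. PCK2, a mitochondrial enzyme of gluconeogenesis, was higher with BPA 0.25 nM than with E2 by 0.51 ± 0.06 (adjusted p = 0.0224). KCTD10 was lower with BPA 2500 nM than with E2 by -0.79 ± 0.06 (adjusted p = 0.00115). By limma 6 loci differed between BPA 0.25 nM and E2 (3 higher, 3 lower) and 5 between BPA 2500 nM and E2 (2 higher, 3 lower; 3 and 3 after rescaling). The dose of E2 is not known, so these are differences between treatments as applied, not at matched doses.

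Between the BPA doses, leaving out DMSO replicate 1, 2 or 3 gave 4 calls each. The calls were 5, 4 and 2 without BPA 0.25 nM replicate 1, 2 and 3, then 6, 7 and 2 without BPA 2500 nM replicate 1, 2 and 3, and 2 without either E2 library. Among the named genes KCTD10 alone kept its call between the doses in each of the 11 fits. COL3A1 lost it without BPA 0.25 nM replicate 1 or 3 or any 1 BPA 2500 nM library (highest adjusted p 0.124). CAMK2N1 lost it in every fit but that without DMSO replicate 1 (highest 0.16), and CCN1, CALCRL and PDLIM3 in all 11 (highest 0.151, 0.153 and 0.191). KCTD10 alone kept its call with only the groups compared in the fit, where COL3A1 was at adjusted p 0.0767.

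For BPA 0.25 nM against E2 the calls were 8 without any 1 DMSO library, and 4, 2 and 7 without BPA 0.25 nM replicate 1, 2 and 3. They were 10, 6 and 10 without BPA 2500 nM replicate 1, 2 and 3, and 213 and 25 without E2 replicate 1 and 2. For BPA 2500 nM against E2 they were 5, 5 and 8 without DMSO replicate 1, 2 and 3, and 5, 5 and 9 without BPA 0.25 nM replicate 1, 2 and 3. They were 7, 4 and 9 without BPA 2500 nM replicate 1, 2 and 3, and 57 and 25 without E2 replicate 1 and 2. PAQR4 and the YWHAE locus kept their calls for both doses, and LBR and KCTD10 for BPA 2500 nM. For the YWHAE locus this is again no check, as its only spread lies between the E2 libraries. LBR lost its call for BPA 0.25 nM without BPA 0.25 nM replicate 1 or 2 (highest adjusted p 0.0603). CTDSP1 lost it for BPA 2500 nM without BPA 2500 nM replicate 2 (adjusted p 0.0529), and for BPA 0.25 nM without any 1 BPA 0.25 nM library or BPA 2500 nM replicate 2 (highest adjusted p 0.11). PCK2 lost it without any 1 BPA 0.25 nM library or E2 replicate 2 (highest adjusted p 0.0975). PAQR4 alone kept its calls with only the groups compared in the fit. The YWHAE locus was then at adjusted p 0.0716 and 0.173, LBR at 0.12 and 0.184 and CTDSP1 at 0.222 and 0.184 for BPA 0.25 nM and 2500 nM, PCK2 at 0.132 and KCTD10 at 0.173. With a pseudocount of 0.1 the YWHAE locus lost both calls as well (adjusted p 0.0565 and 0.0678).

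The changes of BPA 2500 nM and E2 against DMSO overlapped. 15 loci rose in both, where independent lists of 49 and 20 among 12182 would share 0.08. 20 fell in both, where 0.28 would be shared, and 0 were called in opposite directions. 2 further expectations, chosen after seeing the data, compare as many top loci. Unchanged groups that share the DMSO libraries shared 4.2 and 8.7 on average, with at most 9 and 18 in 100 sets. Whole libraries' deviations dealt at random shared 5 and 8.3, with as many as observed in 2 and 9 of 100 sets. SZRD1 and CCDC69, the calls of BPA 0.25 nM, rose in both other comparisons as well, where unchanged groups with shared controls shared both of their top 2 in 12 and 8 of 100 sets and dealt deviations in 41 and 20. Of the 158 loci called for BPA 2500 nM, 156 had the same sign with E2 and 152 with BPA 0.25 nM, at a median 0.83 and 0.48 of the size. Unchanged groups with shared controls gave a ratio of 0.5 and 0.5 (median of 100 sets), and dealt deviations gave ratios as high in 22 and 53 of 100 sets. Groups without any effect that share the DMSO libraries gave the same sign in 79.1% and 82.1% of as many top loci by fold change, and in 87.6% and 90.1% by p, against 98.7% and 96.2% observed. With dealt deviations the share was as high in 32 and 42 of 100 sets. Across the 12182 loci, which are not independent replicates, the Pearson r of fold changes was 0.538 for the BPA doses (0.49 simulated). It was 0.404 for BPA 0.25 nM and E2 (0.443 simulated) and 0.509 for BPA 2500 nM and E2 (0.443 simulated). The covariances were 0.0183, 0.0152 and 0.0220 against 0.0140, 0.0141 and 0.0142 simulated. The differences were 0.00433, 0.00105 and 0.00782 (SD of the simulated values 0.00138, 0.00149 and 0.00136). That simulation treats loci as independent. With dealt deviations the SD was 0.00756, 0.00782 and 0.00815, and the covariance was as high in 40, 56 and 25 of 100 sets and r in 47, 61 and 40, so none of the 3 stands out against it. The dealt spread may itself be too wide, because dealt deviations cancel out within their own group. With 3 DMSO libraries the controls could not be split into groups of at least 2, so part of the excess may come from the shared controls.

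**Figure D3:**
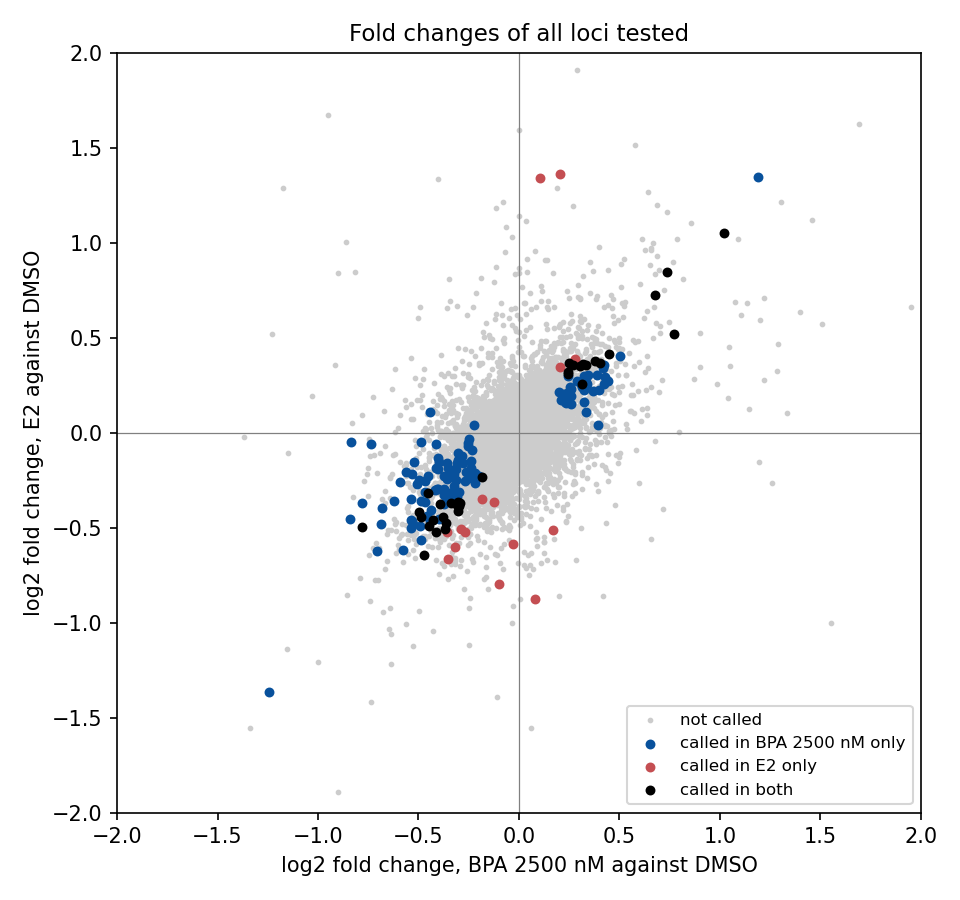
Log2 fold change of each tested locus for BPA 2500 nM (horizontal axis) and E2 (vertical axis) against DMSO, both axes from -2 to 2, with 11 loci outside them. 123 loci were called for BPA 2500 nM only, 16 for E2 only and 35 for both, and the loci called in both lie in the quadrants of equal sign.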

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

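The strand position of the locus named YWHAE was tested only after its values were seen; the differences between treatments were planned. Between the BPA doses, limma found a difference between groups for 6 named genes, as log2 changes of 2500 nM against 0.25 nM: KCTD10 (-0.80), CAMK2N1 (-0.45), PDLIM3 (-0.45), COL3A1 (-0.43), CALCRL (-0.38) and CCN1 (0.36). Against E2, the log2 change with BPA 0.25 nM was -1.22 for PAQR4, 0.58 for CTDSP1, 0.52 for LBR and 0.51 for PCK2, and that with BPA 2500 nM was -1.24 for PAQR4, -0.79 for KCTD10, 0.68 for CTDSP1 and 0.56 for LBR. Of the 10 splits of the 6 BPA libraries into 3 and 3, 1 gave as many as the 8 loci of the real split, which was that split itself (highest other 2), and 10 splits are too few for a share under 0.05.

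The locus named YWHAE (MSTRG.7706) differed from both BPA groups in the same test. It had a mean of 13.6 FPKM in the E2 libraries (7.41 and 19.8) and a listing at 0 in the other 9. The libraries at 0 have no spread, so that test understates the spread of this locus with E2. It is 262 bases long and lies within the annotated span of YWHAE on the other strand. The YWHAE locus on the gene's own strand (MSTRG.7705) stood at 134.9 FPKM in DMSO and 126.3 with E2, a log2 change of -0.093 ± 0.07 (SE; limma adjusted p = 0.609). The bound set for wrong-strand reads, a fall of the gene well beyond its standard error, was not met. So short a locus may take too few reads to lower the gene that far, and the handling of strand is not given. Reads of the abundant gene assigned to the wrong strand and a transcript of its own that appears with E2 therefore cannot be told apart.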

How the results depend on the processing

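The alternatives with array weights, without both E2 libraries, with single-name list members, without a list's most changed member and with only loci naming 1 coding gene were chosen only after the results were seen; the others were planned. Read depth is unknown, so its limits are not known, and tools that need counts (edgeR, DESeq2) were not run because the values are FPKM. Replicate numbers do not pair the libraries (2 of 11 libraries lay closest to 1 of their own number, r of same-number deviations -0.117 to 0.164), so the replicate block removes no known batch. Of 62 called results of named genes, 7 kept their call in every alternative in which they were refitted, and 0 turned direction. This count leaves out the further condition of a log2 fold change of at least 1 and the fit with only loci naming 1 coding gene. Of 123 gene results short of the threshold, 19 passed in some alternative. Of 25 called list results, 10 kept their call in every alternative listed here and 2 turned direction, but 0 of the 25 were called with the correlation estimated from the data, which is not among these alternatives.

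With no filter on low values the loci called were 39 for BPA 2500 nM and 33 for E2 against DMSO, 23 for BPA 0.25 nM against E2 and 19 for BPA 2500 nM against E2. With a mean FPKM of at least 5 they were 0 for BPA 0.25 nM and 102 for BPA 2500 nM against DMSO, the latter with 6 lists. The correlation of BPA 0.25 nM was then 0.487 with BPA 2500 nM and 0.357 with E2. Median-of-ratios scaling gave 1 call for BPA 0.25 nM against DMSO. With no trend or robust setting that count was also 1, and it was 3 between the BPA doses. With only the groups compared there were 9 calls for BPA 0.25 nM, 13 for BPA 2500 nM and 2 for E2 against DMSO, 3 between the BPA doses and 3 for BPA 2500 nM against E2. With the replicate block there were 1 for BPA 0.25 nM, 38 for BPA 2500 nM and 5 for E2 against DMSO, 3 between the BPA doses and 3 for BPA 0.25 nM against E2. With array weights there were 397 for BPA 2500 nM and 5 for E2 against DMSO, and 2 for BPA 0.25 nM against E2. Without both E2 libraries there were 251 for BPA 2500 nM against DMSO and 2 between the BPA doses. Only loci naming 1 coding gene gave 94 for E2 against DMSO. Of the 62 called gene results named, those lost with only the groups compared were 1 of 2 for BPA 0.25 nM, 20 of 24 for BPA 2500 nM and 20 of 20 for E2 against DMSO, 5 of 6 between the BPA doses, 4 of 5 for BPA 0.25 nM against E2 and 4 of 5 for BPA 2500 nM against E2. In that order the replicate block ended 1 (SZRD1, adjusted p 0.362), 5, 16, 4, 3 and 1, no filter 1, 11, 11, 4, 0 and 0, and array weights 0, 0, 16, 0, 3 and 0. A log2 fold change of at least 1 left 0 for BPA 0.25 nM, 3 for BPA 2500 nM and 4 for E2 against DMSO, 0 between the BPA doses, and 2 for each dose against E2. The cause of these moves was not tested.

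Several list calls were lost with a mean FPKM of at least 5: antioxidant enzymes (adjusted p 0.112) and glycolysis and hypoxia (0.176) for BPA 0.25 nM, and DNA damage repair (0.197) and matrix proteases (0.0873) for E2. For BPA 2500 nM it ended the calls of epithelial junctions (0.0707), glycolysis and hypoxia (0.135), matrix proteases (0.062), oxidative phosphorylation (0.14) and TGF-beta targets (0.152). With no filter, epithelial junctions and matrix proteases for BPA 2500 nM (0.289 each) and mitochondrial mRNAs for BPA 0.25 nM (0.244) were lost. The replicate block ended DNA damage repair for E2 (0.0566) and matrix proteases and NRF2 for BPA 2500 nM (0.0513 each). With only the groups compared DNA damage repair for E2 was lost (0.0619), and with no trend or robust setting NRF2 for BPA 2500 nM (0.0549). Single-name list members ended interferon for E2 (0.0598) and NRF2 for both BPA doses (0.0771 and 0.139). Without the most changed member 5 list calls were lost: mitochondrial mRNAs for BPA 0.25 nM (0.0677), epithelial junctions (0.0938) and matrix proteases (0.0774) for BPA 2500 nM, and DNA damage repair (0.0659) and interferon (0.0543) for E2.

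Leaving out 1 library in turn gave 0 to 9 calls for BPA 0.25 nM, 32 to 251 for BPA 2500 nM and 7 to 190 for E2 against DMSO. It gave 2 to 7 between the BPA doses, 2 to 213 for BPA 0.25 nM against E2 and 4 to 57 for BPA 2500 nM against E2. Called lists ranged from 6 to 9, from 6 to 10 and from 5 to 8 in the 3 comparisons with DMSO. The correlations ranged from 0.452 to 0.635 for the BPA doses, from 0.284 to 0.519 for BPA 0.25 nM and E2 and from 0.319 to 0.597 for BPA 2500 nM and E2. The mean of DNA damage repair with E2 ranged from -0.006 to 0.118, and that of oxidative phosphorylation with BPA 2500 nM from -0.013 to 0.054. Genes short of the threshold turned direction too. The log2 change of GPER1 ranged from -0.159 to 0.15, from -0.216 to 0.093 and from -0.392 to 0.369 in the 3 comparisons with DMSO, and that of MKI67 from -0.005 to 0.201, from -0.047 to 0.159 and from -0.104 to 0.102. HMOX1 with E2 ranged from -0.151 to 0.091, and VIM from -0.183 to 0.053 with BPA 2500 nM and from -0.194 to 0.082 with E2. GPER1 was also at 0.012 for BPA 0.25 nM with array weights and at 0.093 for E2 with the replicate block. The cause was not tested.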

Other observations

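The annotation term tests, the dealing of whole libraries' deviations and the test of overlapping loci were chosen only after the results were seen; the other tests were planned. Among 2712 annotation terms of 10 to 300 tested loci, those of ribosome assembly led the rises with BPA 2500 nM and E2. With BPA 2500 nM, rRNA processing rose as a term (156 loci, 9 rose and 0 fell over all loci, median log2 change 0.10, camera adjusted p = 1e-10; adjusted p = 0.975 with an estimated correlation). Ribosome biogenesis (96 loci, 6 rose, median 0.10) and the small-subunit processome (36 loci, 4 rose, median 0.13) rose too, each with adjusted p = 0.975 with an estimated correlation. With E2 the same terms rose, with 4, 2 and 1 called members and medians of 0.11, 0.14 and 0.22, each with adjusted p = 0.751 with an estimated correlation. With BPA 0.25 nM, rRNA processing rose as well (median 0.09, camera adjusted p = 1.24e-07; adjusted p = 0.99 with an estimated correlation) with 0 members called. Structural constituents of the extracellular matrix fell with BPA 2500 nM (28 loci, median -0.12, adjusted p = 0.0465; adjusted p = 0.975 with an estimated correlation), where 1 member rose and 2 fell. They fell with E2 too (median -0.14, adjusted p = 0.000271; adjusted p = 0.751 with an estimated correlation), where 0 members were called. Hormone activity genes fell with E2 (14 loci, median -0.27, adjusted p = 0.00261; adjusted p = 0.751 with an estimated correlation). Camera called 69, 50 and 101 terms in the 3 comparisons with DMSO at the preset correlation, and fry called 0, 268 and 168. None was called with an estimated correlation.

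Fold changes of BPA 2500 nM and E2 against DMSO went together across loci (r = 0.509), with a covariance 0.00782 above the simulated one, but with whole libraries' deviations dealt at random the covariance was as high in 25 of 100 sets and r in 40, so the pattern itself may be chance. After rescaling by the median of ratios, which moved the median fold change by 0.026, the excess was 0.0079. Rescaling shifts all loci of a library by nearly the same amount, which hardly changes a covariance across loci. That test therefore cannot decide on library scaling. GC content and transcript length do not undo the excess, which was 0.00739 after removing a smooth trend on both. It was 0.00654 before, in the 91.7% of loci with a value. Differences of the DMSO libraries alone stay open: the fold changes of BPA 2500 nM against BPA 0.25 nM and of E2 against DMSO, which share no library, had r = 0.174, above the highest of 100 simulated sets (0.169) and so past the bound set beforehand. That bound treated loci as independent and may be too narrow, as dealt deviations gave an r as high in 24 of 100 sets. Dealt deviations cancel out within their own group, so their range of r, -1 to 0.617, may in turn be too wide. A response common to BPA 2500 nM and E2 is a candidate explanation that these 11 libraries leave open.

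SZRD1 and CCDC69 lay apart in DMSO from all 3 treated groups, by -1.02 ± 0.09 and -0.72 ± 0.06 on the log2 scale (DMSO minus the mean of the treated groups, SE). For SZRD1, reads moved to an overlapping or same-named locus are argued against, since the largest rise of such a locus in DMSO was -0.002 on the log2 scale, where the 16.63 FPKM missing from SZRD1 would have raised it by at least 3.97 (if the loci are of like length). For CCDC69 this stays open: the log2 difference of GM2A beside it was 0.079 ± 0.05, and the 1.24 FPKM missing from CCDC69 would have raised it by only 0.17, less than the bound of 0.3. DMSO against the mean of the treated groups called 124 loci (limma; 76 higher, 48 lower), while BPA 0.25 nM, BPA 2500 nM and E2 against the mean of their rest called 0, 14 and 6, with 901 loci at an unadjusted p under 0.05 for the 0. DMSO cultures that drifted apart over 28 days and a response common to every treatment cannot be told apart. Both predict this count, and the design has 1 vehicle group. The treatment labels name DMSO for that group alone, so whether the treated cultures held it too is not known.

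Other splits of the libraries into 3 and 3 were counted for the comparisons of BPA with DMSO. For BPA 2500 nM, 1 of the 10 splits called as many as the real one, which called 158 (highest other 5). For BPA 0.25 nM, 4 of the 10 splits called at least the 2 loci of the real one (highest other 4). In both, 10 splits are too few for a share under 0.05.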
